A study of Mus musculus with 18 samples.

How the data were processed

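Expression was measured on 18 Illumina MouseRef-8 v2.0 beadchip arrays of RNA extracted with Trizol, per the labels' protocols. The arrays form 6 groups of 3: acinar cells, endogenous beta cells, and induced beta cells 7 months, 60 days, 30 days or 10 days old, all from Rag1-deficient mice. Per the labels, endogenous islets were removed and the remaining acinar fraction was digested to single cells before induced cells were sorted. Groups and replicate numbers were taken from the sample titles. The number of arrays limits the precision of every value, and nothing in the labels says whether arrays of a group came from separate animals.

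The authors deposited 1 table with a signal intensity and a detection p-value for each of 18118 gene symbols on each array, per the file headers. The deposited signal intensities differed in their medians from 56.8 to 81.6 between arrays and showed no background subtraction. The deposited detection p-value compares a gene with negative controls on the same array, and most values were multiples of 1 over 798. The deposited series matrix held log10 values for 18112 of the symbols, with 6 missing, equal to log10 of the same signals to within 5.5e-10, so that it is uncentred and had column medians of 1.75 to 1.91. Software, background handling and the summary of probes to gene symbols are not given in the sources used here. The table holds a single value per symbol, so a choice among the probes of a gene, planned before the data were examined, did not apply. In the 7-month columns 80 values of 27 genes carry up to 10 digits, against at most 7 elsewhere, and they were used as deposited.

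Signals were corrected for background by normexp with limma 3.58.1 in R 4.3.3, with the mean and SD of the negative controls inferred from detection p-values, an offset of 16, and quantile normalization between arrays, followed by log2. Limma's own inference uses every detection p-value, but part of them lie off the grid of 798 steps in this table, so the controls were inferred from genes on the grid alone. A test on simulated data showed that the first version of this step gave too large an SD, and it was corrected after the first counts of called genes had been seen. The corrected step returned 0.9998 times the true SD in simulated arrays. Genes with a detection p-value under 0.01 on at least 3 arrays were tested, which left 8942 genes and left out 9176 dim ones. Symbols were matched to a table of current mouse gene names, in which 17257 were found and 4903 were updated, and the file's symbol was kept otherwise. No genome or coordinates were used here.

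All 18 arrays entered 1 model with limma's lmFit and eBayes (prior degrees of freedom 2.98), with 13 comparisons between groups and an F-test over the 4 induced times, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. A gene not measured on any array of a group has only a bound there, where measured means a detection p-value under 0.01 and a signal above the mean of the array's negative controls. Its change is given as at least N-fold, from the brighter group's mean against the mean, per array, of the higher of a floor (5.02 to 6.12 on the log2 scale) and the gene's own value. The floor was the lowest detected signal among genes whose detection p-value lies on the grid. In a list's median at bounds, an unmeasured gene without a bound over 1-fold counts as 0. A named gene measured on some arrays of the dimmer group but under the floor on at least 1 of them is given as a bound in the same way. The demand on the signal, this floor, the count as 0 and the last rule were set after the values had been seen, because the lowest detected signals of the acinar arrays had been those of Ins1, under the negative controls, and they had made the earlier bounds too large. The filter, the model and the calls do not use them. Position between acinar and beta cells was the projection of an array on the difference of the group means over the genes called between them, with an acinar or beta array left out of its own reference mean, and was tested with permutation tests over all assignments, which ignore the pairing of late arrays described below. In simulated data for the comparison of 7 months with day 60, with 8942 genes of which 200 were changed, 78.0% of genes changed 1.5-fold and 94.5% of genes changed 2-fold were called, and 5.57% of calls were unchanged genes. The simulated noise was independent, with each gene's spread pooled over all groups. It left out the larger spread of the late arrays and their pairing described below.

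Gene lists, comparisons, tests, the rule for named genes and most alternatives were fixed before the data were examined. The 27 lists were digestive enzymes, acinar secretory and zymogen granule proteins, acinar transcription factors, islet transcription factors, insulin, granule and prohormone processing genes, glucose sensing and exocytosis genes, beta-cell maturity genes, genes normally silenced in beta cells, endocrine progenitor genes, other islet hormone cell markers, duct cell markers, acinar injury genes, macrophage and myeloid markers, lymphocyte markers, endothelial markers, mesenchymal and stellate markers, red blood cell markers, interferon-stimulated genes, antigen presentation genes, unfolded protein response genes, immediate early and heat shock genes, oxidative phosphorylation genes, glycolysis genes, ribosomal protein genes, cell cycle genes, cholesterol synthesis genes and neuronal genes shared with islets. Of 631 listed members 593 were in the table and 455 were tested, and some genes stand in several lists. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 351 tests of 27 lists in 13 comparisons, which called 131 of them, against 41 with the correlation estimated from the residuals. The text gives lists chosen from these results. Named genes were the 8 with the largest rise and the 8 with the largest fall among called genes whose groups do not overlap, members of the lists with the smallest p, fixed islet and acinar genes such as Ins1, Ucn3, Pdx1, Mafa, Neurog3, Ptf1a and Cpa1, and the 8 genes with the widest range over the induced times. Names without a gene symbol were passed over, as were intelectin genes whose current names were in doubt.

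Replicate numbers are shared by all groups, and it was checked whether they pair arrays. Deviations from the group means correlated at 0.790 to 0.862 between same-numbered arrays of day 60 and 7 months, and at −0.037 to 0.069 in the 42 other same-numbered pairs, so the numbers were taken to pair arrays of these late groups alone. Alternatives were median scaling without quantile normalization, no background correction, normexp with an offset of 50 and no detection p-values, the series matrix, no filter on dim genes, a detection p-value under 0.05, the replicate number as a block, only the groups compared, eBayes with trend and robust, array weights, camera with an estimated correlation, fry, position over all detected genes and without the enzyme and insulin lists, and leaving out each array. Chosen after seeing the data were limma's own inference of the negative controls, leaving out the 27 genes with more digits, leaving out the 7-month arrays (also for position), counting each tight triplicate as 1 sample, the block within the 6 late arrays, and day 60 in place of 7 months. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.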

Results

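Gene expression was measured with mouse beadchip arrays in pancreatic cells of mice that lack Rag1, a gene needed to make T and B cells. The 18 arrays fell into 6 groups of 3: acinar cells, which make digestive enzymes, endogenous beta cells, which make insulin, and induced beta cells collected after 10, 30 or 60 days or after 7 months. Per the labels, beta cell formation was induced by an adenovirus injected into the splenic lobe of the pancreas, and induced cells were sorted by a red fluorescent protein. The labels do not name the genes that the virus carried. Between 5990 and 7745 of 18118 gene symbols had a detection p-value under 0.01 on an array, with the fewest on acinar arrays, and 8942 genes were tested. The 50 brightest genes held 25.3% to 27.8% of the signal of the acinar arrays and 10.1% to 10.7% of that of the beta arrays. Values below are normalized log2 intensities, differences are given with their standard error (SE) and n = 3 arrays per group unless stated, and adjusted p-values come from limma. The SE of a gene rests on a spread pooled over all 6 groups, so it need not match the spread of the groups compared. Nothing in the labels says that the arrays of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. Sex did not enter the model, although signals of Y chromosome genes differed between groups, as given below. A gene not measured above background on any array of the dimmer group has only a bound, given as at least N-fold, and a list's median at bounds takes such genes at their bound, or at 0 where they have none. The size of a list's median often depended on the settings: in 65 of 82 called lists described here at least 1 of 9 other settings moved it over 1.5 times, and its lowest and highest value over these settings then follow as its range. A list of genes was called by limma's camera test, and its counts adjusted over the list alone were those over all genes wherever no other count is given.

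The first comparison set the target cell against the starting cell. Ins1, an insulin gene, was at least 458-fold higher in endogenous beta cells than in acinar cells (adjusted p = 9.9e-20). Its acinar signals of 38.5 to 44.9 lay below the mean of the negative controls, although the deposited detection p-values of 0.0047 to 0.0062 pass as detected, so they were taken as not measured. Chgb, which encodes a chromogranin of secretory granules, was not detected in acinar cells and was at least 248-fold higher in beta cells. Cuzd1, which encodes a zymogen granule membrane protein, and Prss3, a trypsinogen gene, were not detected in beta cells and were at least 542-fold and at least 490-fold lower there. Of 23 tested genes for insulin, granules and prohormone processing, 21 rose and 2 were not called (median 6.10, or 5.15 at bounds, adjusted p = 6.2e-10). All 24 digestive enzyme genes fell, with a median of −5.73, or −5.62 at bounds (adjusted p = 6.2e-16). Ctrl, a chymotrypsin-like protease gene, fell by 5.52 ± 0.057. Of 18 genes for acinar secretory and zymogen granule proteins, 17 fell and 1 was not called (median −6.43, or −6.17 at bounds, adjusted p = 2.4e-10). Ptf1a, a transcription factor of acinar cells, was at least 54.5-fold lower in beta cells.

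Of 13 islet transcription factors, 11 rose and 2 were not called in beta cells (median 4.13, or 2.72 at bounds, range 1.03 to 4.36, adjusted p = 0.00019), among them Insm1, a zinc finger factor of endocrine cells, at least 47.5-fold higher. With an estimated correlation this list had adjusted p = 0.0607, and it was not called in the series matrix (median 3.62, adjusted p = 0.0651). Of 21 glucose sensing and exocytosis genes, 19 rose, 1 fell and 1 was not called (median 2.22, or 1.68 at bounds, range 0.62 to 3.03, adjusted p = 2.9e-05). Of 14 beta-cell maturity genes 13 rose and 1 fell (median 4.17, or 3.64 at bounds, range 1.16 to 4.84, adjusted p = 4.8e-05). Among the maturity genes, Ucn3, which encodes the islet peptide urocortin 3, was at least 18.1-fold higher. The counts of rises can hold genes near background. Mafa, a maturity gene and islet transcription factor, differed by 0.07 with limma's own inference of the negative controls (adjusted p = 0.504). Neurog3, an islet transcription factor, differed by 0.12 there (adjusted p = 0.481). In the main fit both were called higher. Neuronal genes shared with islets rose in 16 of 17 cases and fell in 1, with a median of 2.47, or 1.01 at bounds, range 0.49 to 2.75 (adjusted p = 1.7e-05). Syn1, a synaptic vesicle gene, was at least 18.8-fold higher. The 5 acinar transcription factors fell (median −1.47, or −1.22 at bounds, range −1.65 to −0.40, adjusted p = 0.00973, adjusted p = 0.107 with an estimated correlation), although Bhlha15 was 0.09 higher in the series matrix values. Glycolysis genes had 13 of 16 higher, 2 lower and 1 not called (median 2.04, or 1.64 at bounds, range 1.26 to 2.92, adjusted p = 0.0014, adjusted p = 0.0607 with an estimated correlation). The glycolysis call was lost with median scaling (median 2.92, adjusted p = 0.108) and in the matrix (median 2.77, adjusted p = 0.176), where the list's median was larger but so was that of all genes. Of 18 genes normally silenced in beta cells, 15 were lower in beta cells, 1 was higher and 2 were not called (median −2.90, or −2.59 at bounds, range −2.90 to −0.98, adjusted p = 2.6e-05, adjusted p = 0.342 with an estimated correlation).

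Markers of other cells also separated these groups. Dcn, which encodes the matrix protein decorin, was at least 71.1-fold lower in beta cells than in acinar cells. Of 19 mesenchymal and stellate markers 18 fell (median −2.94, or −2.16 at bounds, range −2.94 to −0.54, adjusted p = 0.00022, adjusted p = 0.561 with an estimated correlation). Macrophage and myeloid markers fell in 21 of 24 cases and rose in 2 (median −1.62, or −1.01 at bounds, range −1.62 to −0.33, adjusted p = 0.00062, adjusted p = 0.621 with an estimated correlation). Of 14 endothelial markers 13 fell and 1 rose (median −2.79, or −2.42 at bounds, range −2.79 to −0.89, adjusted p = 0.00033, adjusted p = 0.292 with an estimated correlation). Among them Esam fell by 1.44 but differed by −0.10 with median scaling and was 0.31 higher in the matrix. Cell cycle genes had 11 of 14 lower, 2 higher and 1 not called (median −1.54, or −1.48 at bounds, range −1.54 to −0.07, adjusted p = 0.00513, adjusted p = 0.107 with an estimated correlation). The hemoglobin gene Hba-a1 was at least 326-fold lower in beta cells. The 5 red blood cell markers each fell but were not called as a list (median −4.33, or −3.52 at bounds, adjusted p = 0.0512). They were called lower with median scaling (median −3.54, adjusted p = 0.0013), in the matrix (median −2.24, adjusted p = 9.2e-05), in each of the 3 other settings of background correction (adjusted p = 0.0263 to 0.0393), with both other filters on dim genes (adjusted p = 0.0305 and 0.0405) and with the replicate block (adjusted p = 0.0438), but not with an estimated correlation (adjusted p = 0.482). They were also called without day 60 replicate 1, 2 or 3 (adjusted p = 0.0308, 0.0490 and 0.0431) and without 7-month replicate 1 or 2 (adjusted p = 0.0291 and 0.0470). The 8 markers of other islet hormone cells were not called (median 2.91, adjusted p = 0.0523, 6 higher, 1 lower), but were called higher with both other filters on dim genes (medians 0.19 and 2.28, adjusted p = 0.0324 and 0.0430). They were also called without day 60 replicate 1 or 3 (adjusted p = 0.0463 and 0.0488), without 7-month replicate 1 or 3 (adjusted p = 0.0446 and 0.0419) and without beta replicate 1, 2 or 3 (adjusted p = 0.0394, 0.0395 and 0.0451). Gcg, the glucagon gene of alpha cells, was 2.54 ± 0.38 higher in beta cells and had a level of 12.02 ± 0.028 (SD) in acinar cells. The 13 cholesterol synthesis genes were not called (adjusted p = 0.116, 8 higher, 2 lower), except with no filter on dim genes (adjusted p = 0.0436). Insig1, detected on 1 of 3 acinar arrays and on none of beta cells, where it was at least 2.70-fold lower, was 0.03 higher in the matrix. In all, 7106 of 8942 genes were called between these cells, 3766 higher and 3340 lower in beta cells, with 3558 past 2-fold. The split depended on scaling, with 53.0% of called genes higher after quantile normalization, 80.4% after median scaling and 88.4% in the series matrix, where the median of all genes moved to 0.95 and 1.06.

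Day 10 was compared with acinar cells to see what had changed soon after induction. Ins1 was at least 82.1-fold higher in induced cells, and Ins2 at least 340-fold, with acinar signals over the negative controls' mean on 2 of 3 arrays and under the floor for bounds on all 3. The gut and islet hormone genes Ghrl, for ghrelin, and Gip, for the incretin GIP, were not detected in acinar cells and were at least 240-fold and at least 281-fold higher. Mafa and Neurog3, transcription factors used to convert acinar cells to beta cells, were at least 5.82-fold and at least 3.86-fold higher. The arrays do not separate a viral copy from the cell's own. Pdx1, the other factor used for that purpose, fell by 0.53 ± 0.097, but was 0.08 higher with median scaling and 0.35 higher in the matrix. Insulin, granule and prohormone processing genes rose in 18 of 23 cases and fell in 2 (median 3.43, or 1.99 at bounds, range 1.18 to 3.43, adjusted p = 6.8e-06, adjusted p = 0.0722 with an estimated correlation). Of the 13 islet transcription factors 11 rose and 2 fell (median 3.17, or 1.92 at bounds, range 0.75 to 3.17, adjusted p = 0.0011, adjusted p = 0.0942 with an estimated correlation). Of 21 endocrine progenitor genes, 17 rose and 2 fell (median 2.38, or 1.42 at bounds, range 0.54 to 2.48, adjusted p = 0.00035). Cdkn1a, a cell cycle inhibitor gene detected on 2 of 3 acinar arrays, rose by 3.94 ± 0.085. Glucose sensing and exocytosis genes rose in 15 of 21 cases and fell in 2 (median 1.71, or 0.60 at bounds, range 0.23 to 1.71, adjusted p = 0.0020, adjusted p = 0.0759 with an estimated correlation).

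Digestive enzyme genes stayed near the acinar level at day 10. Of 24, 6 fell and 18 were not called (median −0.08, adjusted p = 0.206). The carboxypeptidase gene Cpa1 was at 14.12 ± 0.058 (SD) against 14.21 ± 0.028 in acinar cells. This result depended on scaling, since the list's median was −0.40 with median scaling and −0.15 in the matrix. The list was called lower than other genes in both, where the median of all genes lay at 0.42 and 0.60. Ctrc, a chymotrypsin gene, fell by 3.12 ± 0.17 and Serpini2, a pancreatic serpin gene, by 4.95 ± 0.26. Immediate early and heat shock genes rose in 17 of 19 cases and fell in 1 (median 1.52, or 1.51 at bounds, range 1.41 to 2.75, adjusted p = 4.5e-05, adjusted p = 0.0722 with an estimated correlation). Glycolysis genes rose in 14 of 16 cases and fell in 1 (median 1.54, or 1.17 at bounds, adjusted p = 0.00043). Dcn fell by 5.49 ± 0.27, with 17 of 19 mesenchymal markers lower (median −1.91, or −1.73 at bounds, range −1.91 to −0.51, adjusted p = 0.0043, adjusted p = 0.664 with an estimated correlation). Emcn, an endothelial sialomucin gene, was at least 16.5-fold lower, with 11 of 14 endothelial markers lower (median −1.72, or −1.35 at bounds, range −1.72 to −0.35, adjusted p = 0.0051, adjusted p = 0.407 with an estimated correlation). Hba-a1 fell by 6.46 ± 0.73, while the red blood cell list (1 higher, 4 lower, median −4.24, or −3.09 at bounds) was not called (adjusted p = 0.206), but was called lower with median scaling (median −3.31, adjusted p = 0.0324) and in the matrix (median −1.85, adjusted p = 0.0012). Antigen presentation genes rose in 10 of 11 cases and fell in 1 (median 1.55, range 0.76 to 2.31, adjusted p = 0.0201, adjusted p = 0.402 with an estimated correlation). Macrophage markers rose in 18 of 24 cases and fell in 3 (median 1.09, range 0.42 to 1.63, adjusted p = 0.0264, adjusted p = 0.747 with an estimated correlation). Both calls were lost with median scaling (medians 2.31 and 1.63, adjusted p = 0.0532 and 0.0656) and in the matrix (medians 2.18 and 1.54, adjusted p = 0.140 and 0.208), where these medians were larger but so was that of all genes. The macrophage call was also lost without acinar replicate 2 (median 1.10, adjusted p = 0.0508), and the mesenchymal call with limma's own inference of the negative controls (median −0.51, adjusted p = 0.0704). The comparison called 7134 genes, 3592 higher and 3542 lower, 3663 of them past 2-fold. The share higher was 50.4%, against 69.4% with median scaling and 85.5% in the matrix, where the all-gene median lay at 0.42 and 0.60.

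At day 30, Ins1 was at least 313-fold above acinar cells and Ucn3 was at least 15.1-fold higher. Of the 23 insulin and granule genes, 22 rose and 1 fell (median 4.04, or 3.01 at bounds, range 2.32 to 4.26, adjusted p = 4.2e-09). Beta-cell maturity genes rose in 12 of 14 cases and fell in 2 (median 3.28, or 2.54 at bounds, range 1.20 to 3.75, adjusted p = 0.00021). G6pc2, an islet glucose phosphatase gene, rose by 4.77 ± 0.098. Endocrine progenitor genes rose in 15 of 21 cases and fell in 3 (median 2.82, or 1.69 at bounds, range 0.72 to 2.82, adjusted p = 0.00049), and Chgb was at least 145-fold higher. Neuronal genes shared with islets rose in 13 of 17 cases and fell in 3 (median 2.37, or 1.09 at bounds, range 0.33 to 2.41, adjusted p = 0.0012), a call lost in the matrix (median 1.98, adjusted p = 0.0951). Immediate early and heat shock genes rose in 18 of 19 cases (median 2.75, adjusted p = 1.6e-07), with the inducible heat shock protein gene Hspa1a at least 38.0-fold higher and the transcription factor gene Fosb higher by 4.93 ± 0.090. Digestive enzymes had 8 of 24 lower, 7 when adjusted over the list alone, and the list was not called (median −0.03, adjusted p = 0.206). Its median was −0.71 with median scaling and −0.23 in the matrix. The enzyme list was called lower than other genes in both, where the all-gene median lay at 0.68 and 0.93. Of 18 acinar secretory proteins 11 fell and 2 rose (median −0.21, range −0.79 to −0.21, adjusted p = 0.0353, adjusted p = 0.458 with an estimated correlation), among them Aqp12, an acinar water channel gene, by 3.22 ± 0.076. Ptf1a fell by 1.79 ± 0.20 but differed by −0.16 in the matrix (adjusted p = 0.450), and Tead2, a factor of the Hippo pathway, by 4.47 ± 0.16. Pdx1 fell by 0.78 ± 0.097, but was 0.17 higher with median scaling and 0.57 higher in the matrix. The comparison called 7098 genes, 3546 higher and 3552 lower, 3368 past 2-fold. Of called genes 49.96% were higher, against 77.9% with median scaling and 93.6% in the matrix, where the all-gene median lay at 0.68 and 0.93.

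The late induced groups were set against acinar cells in the same way. Their same-numbered arrays deviated together and lay close to each other, as given below. Matching values at day 60 and 7 months are therefore not independent findings. Rfx6, a factor required to form islet endocrine cells, was at least 70.5-fold higher at day 60 and at least 68.6-fold higher at 7 months. Hspa1a was at least 143-fold and at least 139-fold higher, and all 19 immediate early and heat shock genes rose at both times (medians 3.06 and 3.11, adjusted p = 6.7e-10 and 7.3e-10). Of 13 islet transcription factors 12 rose at each time (medians 3.57 and 3.63, or 2.24 and 2.31 at bounds, ranges 1.03 to 3.57 and 1.07 to 3.63, adjusted p = 4.6e-06 and 5.2e-06). Beta-cell maturity genes rose in 11 of 14 cases and fell in 3 at each time (medians 3.93 and 3.91, or 2.85 and 2.86 at bounds, ranges 1.93 to 3.93 and 1.94 to 3.91, adjusted p = 0.00022 and 0.00023). Slc2a2, the glucose transporter gene of beta cells, was at least 12.2-fold and at least 12.4-fold higher. Glucose sensing and exocytosis genes rose at day 60 in 18 of 21 cases and fell in 1 (median 1.87, or 1.18 at bounds, range 0.63 to 2.19, adjusted p = 5.2e-06). Serpini2 fell by 5.10 ± 0.26 and 5.13 ± 0.26, and Gatm, a creatine synthesis gene, was at least 13.1-fold and at least 14.7-fold lower. Oxidative phosphorylation genes fell in 22 of 29 cases and rose in 2 at each time (medians −0.55 and −0.50, ranges −0.60 to 0.42 and −0.55 to 0.28, adjusted p = 0.00084 and 0.00077, adjusted p = 0.237 and 0.234 with an estimated correlation). In the matrix their medians were 0.42 and 0.28, above 0 but below those of all genes, and they were called lower than other genes (adjusted p = 0.0081 and 0.0033). Cell cycle genes at 7 months had 11 of 14 lower and 2 higher (median −1.70, or −1.34 at bounds, range −1.70 to −0.28, adjusted p = 0.0017, adjusted p = 0.0722 with an estimated correlation).

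Digestive enzymes at day 60 had 8 of 24 lower and 1 higher, or 6 lower when adjusted over the list alone (median −0.07, adjusted p = 0.194). At 7 months 7 were lower and 1 higher, again 6 lower over the list alone (median −0.08, adjusted p = 0.206). With median scaling the medians of these times were −0.94 and −0.86 and in the matrix −0.50 and −0.46. The enzymes were called lower than other genes in each case, where the all-gene medians were positive. Ptf1a fell by 0.84 ± 0.20 and 0.80 ± 0.20, with values of −0.01 and −0.07 under median scaling and rises of 0.43 and 0.32 in the matrix. Pdx1 differed by −0.03 and −0.07 and was not called (adjusted p = 0.813 and 0.520), but rose by 0.89 and 0.75 with median scaling and by 1.11 and 0.95 in the matrix. The 7-month values of 27 genes, among them Ins1, Ins2, Ucn3, Iapp, Rfx6, Slc2a2, G6pc2 and Chgb, were deposited with up to 10 digits, against at most 7 for all other values. Without these 27 genes, which are strong members of the lists, maturity genes were not called at day 60 (median 2.79, adjusted p = 0.304), at 7 months (median 2.81, adjusted p = 0.306) or at day 30 (median 2.69, adjusted p = 0.145). In beta cells against acinar cells the maturity genes and islet transcription factors were then not called either (medians 1.16 and 1.27, adjusted p = 0.0629 and 0.0801), nor were islet transcription factors at day 10 (median 2.19, adjusted p = 0.202). Differences between groups other than 7 months hold none of the values with more digits. Calls lost there show only how far a list rests on these genes. Against acinar cells 6887 genes were called at day 60, 3361 higher, 3526 lower and 2974 past 2-fold, and 6949 at 7 months, 3383 higher, 3566 lower and 3042 past 2-fold. The share higher was 48.8% and 48.7%, against 77.1% and 74.7% with median scaling and 92.4% and 90.2% in the matrix, where the all-gene medians lay at 0.58 and 0.50 and at 0.82 and 0.72.

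**Figure D1:**
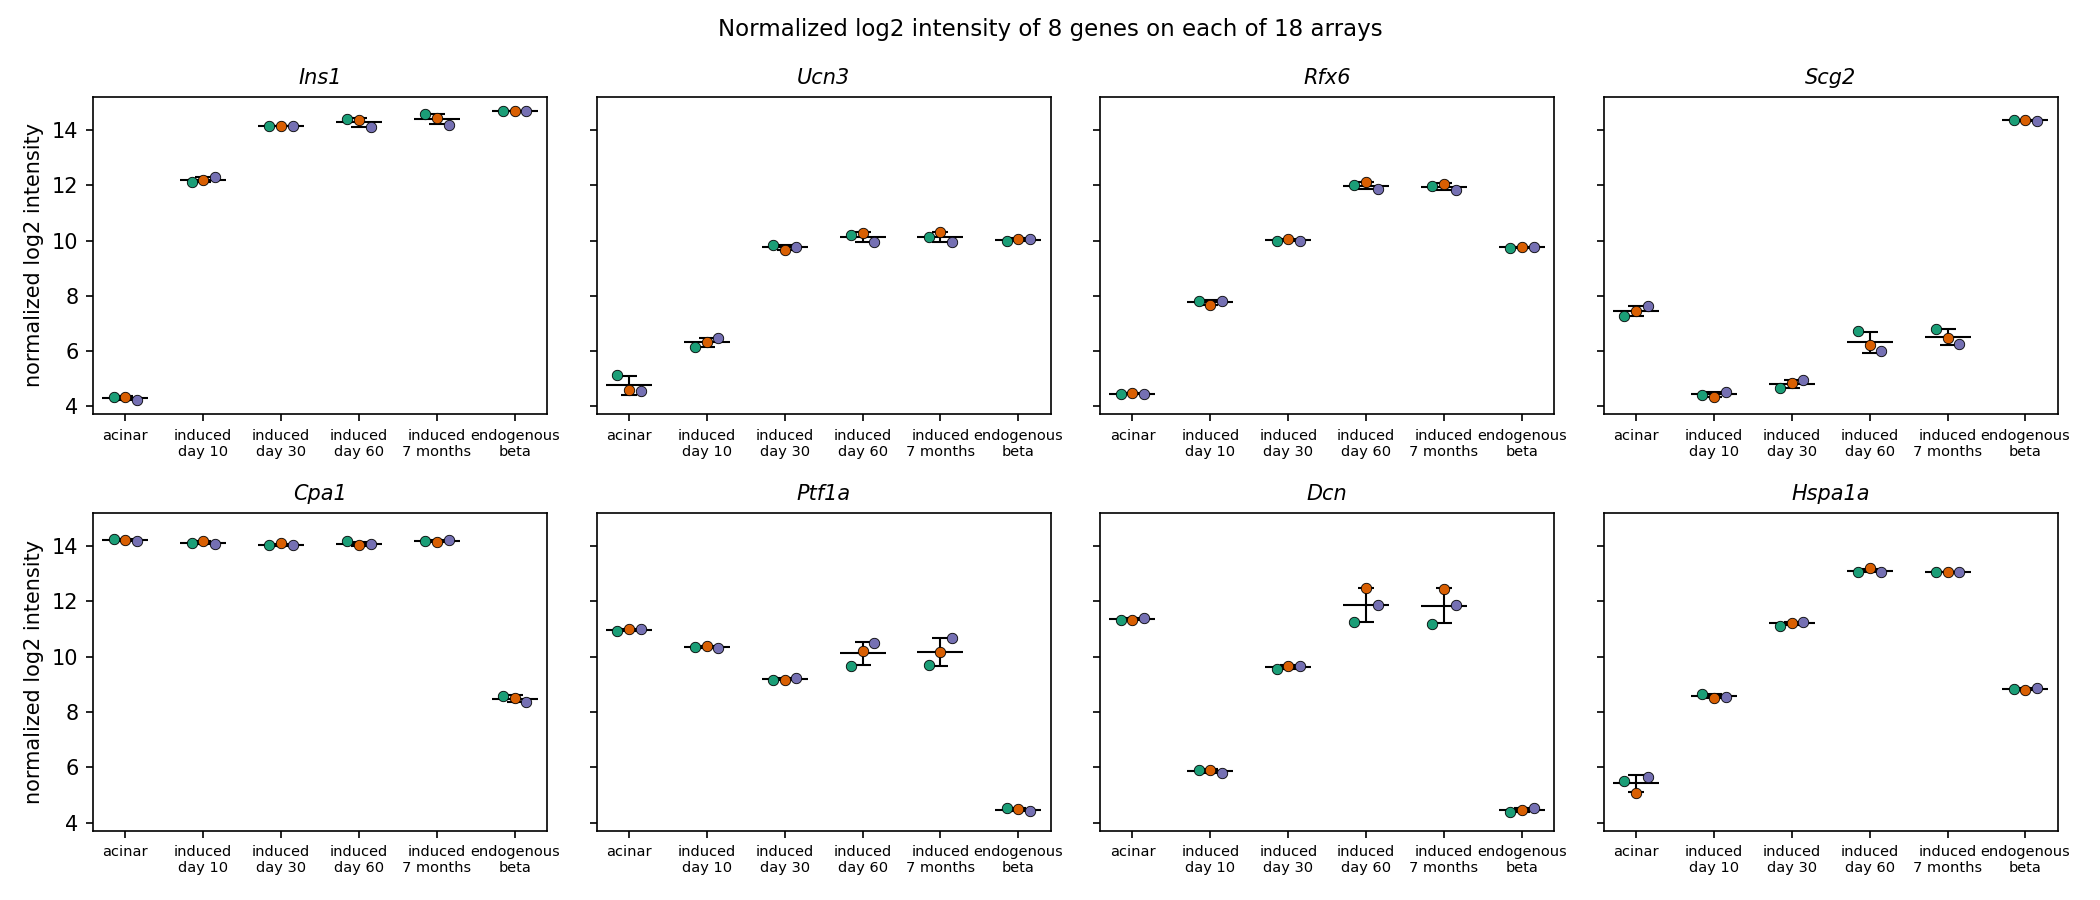
Normalized log2 intensity (vertical axis) of 8 genes on each of the 18 arrays in 6 groups (horizontal axis), where points are arrays coloured by replicate number, wide bars are group means and whiskers are SD. Ins1 was at 4.31, below background, in acinar cells, 12.2 at day 10 and 14.7 in beta cells, Scg2 was at 7.45 in acinar cells, 4.44 at day 10 and 14.3 in beta cells, and Cpa1 was at 14.1 at day 10 and 8.49 in beta cells.

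Induced cells were next compared with endogenous beta cells, the target. At day 10 the secretogranin gene Scg2 was not detected and lay at least 416-fold below beta cells, Isl1, a factor of islet cell formation, at least 72.9-fold below, and Pdyn, for the opioid precursor prodynorphin, at least 142-fold below. Ins1 fell by 2.48 ± 0.092 relative to beta cells, where Ins2 ranked 1 and Ins1 ranked 5 from the brightest on each of the 3 arrays, so that their differences from beta cells are limited by the brightest signals the arrays gave. Ins2 fell by 0.61 ± 0.20 but was 0.02 higher with median scaling and differed by −0.17 in the matrix (adjusted p = 0.172). The hormone genes of other islet cells were also lower at day 10, Gcg by 4.98 ± 0.38, Sst, for somatostatin, by 3.55 ± 0.25 and Ppy, for pancreatic polypeptide, by 5.31 ± 0.42, from 14.56, 14.22 and 12.43 in the beta samples. Whether alpha, delta and PP cells in the beta samples account for part of the islet genes that were lower in induced cells was not tested. Insulin and granule genes were lower in 20 of 23 cases and higher in 2 (median −2.0, adjusted p = 4.1e-05, adjusted p = 0.106 with an estimated correlation). Maturity genes were lower in 11 of 14 cases and higher in 1 (median −1.46, range −1.57 to −0.80, adjusted p = 0.0037, adjusted p = 0.0722 with an estimated correlation and a median of −0.80 with adjusted p = 0.296 without the 27 genes with more digits). Neuronal genes were lower in 13 of 17 cases and higher in 2 (median −1.22, or −0.98 at bounds, range −1.45 to −0.26, adjusted p = 0.0027). All 24 digestive enzymes were higher than in beta cells (median 5.36, adjusted p = 1.6e-15), and Ptf1a was at least 35.8-fold higher. Ghrl, detected on 1 of 3 beta arrays, was at least 372-fold higher, Gip at least 418-fold, and Gal, for the peptide galanin, by 8.12 ± 0.13. Of 18 genes normally silenced in beta cells 15 were higher (median 2.35, or 1.84 at bounds, range 0.76 to 2.35, adjusted p = 4.2e-05, adjusted p = 0.358 with an estimated correlation). Macrophage markers were higher in 22 of 24 cases (median 2.81, or 1.85 at bounds, range 1.23 to 2.81, adjusted p = 3.5e-06, adjusted p = 0.482 with an estimated correlation), with Cd74, the invariant chain of antigen presentation, at least 31.4-fold higher. The comparison called 7151 genes, 3403 higher and 3748 lower, 3575 past 2-fold. Of called genes 47.6% were higher, against 36.6% with median scaling and 34.9% in the matrix, where the all-gene median lay at −0.32 and −0.29.

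At day 30 Scg2 remained undetected, at least 522-fold below beta cells, and Isl1 was at least 91.6-fold below. Ins1 fell by 0.55 ± 0.092, while Ins2 differed by −0.16 ± 0.20 (adjusted p = 0.465) and Ucn3 by −0.27 ± 0.14 (adjusted p = 0.108). With only the groups compared in the model, limma called Ins2 and Ucn3 lower (adjusted p = 0.0051 and 0.0022). The Ins1 difference was −0.09 with median scaling and −0.05 in the matrix (adjusted p = 0.485 and 0.671), and Ucn3 was called lower in both (−0.28 and −0.22, adjusted p = 0.0203 and 0.0207). Insulin and granule genes were lower in 16 of 23 cases and higher in 4 (median −0.77, range −0.79 to −0.43, adjusted p = 0.0091, adjusted p = 0.331 with an estimated correlation), a call lost with median scaling (median −0.54, adjusted p = 0.187), in the matrix (median −0.43, adjusted p = 0.0721) and without the 27 genes above (median −0.69, adjusted p = 0.125). All 24 digestive enzymes were higher (median 5.34, adjusted p = 1.0e-18). Immediate early and heat shock genes were higher in 17 of 19 cases and lower in 2 (median 2.05, adjusted p = 6.2e-07), with Hspb1, a small heat shock protein gene, higher by 6.29 ± 0.072. Of 21 acinar injury genes 16 were higher and 1 lower, or 2 lower when adjusted over the list alone (median 2.09, or 1.45 at bounds, range 0.92 to 2.28, adjusted p = 4.3e-05, adjusted p = 0.0563 with an estimated correlation). Among them Reg3d, a secreted lectin gene of injured pancreas, was at least 222-fold higher. Duct cell markers were higher in 14 of 21 cases and lower in 4, or 5 over the list alone (median 1.29, or 1.19 at bounds, range 0.24 to 1.38, adjusted p = 0.0166, adjusted p = 0.482 with an estimated correlation). The duct call was lost with limma's own inference of the negative controls (median 0.24, adjusted p = 0.0569). The comparison called 6656 genes, 3091 higher and 3565 lower, 2660 past 2-fold, and the all-gene median lay at −0.14 with median scaling.

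At day 60 and 7 months Scg2 fell by 8.02 ± 0.16 and 7.83 ± 0.16 relative to beta cells, and Pdyn was at least 164-fold and at least 184-fold lower. Here too, matching values at these times are not independent findings, because same-numbered late arrays deviated together. Ins1 fell by 0.41 ± 0.092 and 0.30 ± 0.092, calls that were lost with median scaling (−0.23 and −0.05, adjusted p = 0.0698 and 0.661) and in the matrix (−0.22 and −0.09, adjusted p = 0.0511 and 0.402). Ucn3 differed by 0.11 ± 0.14 and 0.10 ± 0.14 and was not called (adjusted p = 0.488 and 0.530), but was lower by −0.24 and −0.36 with median scaling and by −0.22 and −0.39 in the matrix. All 24 digestive enzymes were higher at both times (medians 5.38 and 5.39, adjusted p = 5.8e-19 for each), and Ptf1a was at least 30.4-fold and at least 31.4-fold higher. Immediate early and heat shock genes were higher in 17 of 19 cases with 1 lower at day 60 and in 18 with 1 lower at 7 months (medians 3.07 for both, adjusted p = 7.6e-09 and 7.8e-09). Mesenchymal and stellate markers were higher in 19 of 19 and 18 of 19 cases (medians 3.25 and 3.27, or 2.95 and 2.97 at bounds, ranges 1.11 to 3.25 and 1.12 to 3.27, adjusted p = 1.3e-05 and 1.5e-05, adjusted p = 0.482 with an estimated correlation for both), with Dcn at least 102-fold and at least 99.8-fold higher. At day 60 endothelial markers were higher in 11 of 14 cases and lower in 1 (median 1.67, or 1.12 at bounds, range 0.21 to 1.69, adjusted p = 0.0016, adjusted p = 0.342 with an estimated correlation). Genes normally silenced in beta cells were higher in 16 of 18 cases and lower in 1 (median 2.23, or 2.07 at bounds, range 0.88 to 2.23, adjusted p = 2.8e-06, adjusted p = 0.295 with an estimated correlation). At 7 months macrophage markers were higher in 20 of 24 cases (median 2.41, or 2.10 at bounds, range 0.67 to 2.41, adjusted p = 4.9e-06, adjusted p = 0.482 with an estimated correlation). Insulin and granule genes were lower in 15 of 23 cases and higher in 4 (median −0.88, range −1.57 to −0.76, adjusted p = 0.0148, adjusted p = 0.358 with an estimated correlation), a call lost with median scaling (median −1.08, adjusted p = 0.154) and in the matrix (median −0.79, adjusted p = 0.0867). Day 60 gave 6949 called genes, 3091 higher, 3858 lower and 2852 past 2-fold, and 7 months 6962, 3103 higher, 3859 lower and 2878 past 2-fold. The share higher was 44.5% and 44.6%, against 33.2% and 30.0% with median scaling and 36.0% and 31.1% in the matrix, where the all-gene medians lay at −0.34 and −0.42 and at −0.22 and −0.32.

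How far the induced cells lay along the way from acinar to beta cells was measured on the 7106 genes called between those cells, with 0 at the acinar mean and 1 at the beta mean. These genes include markers of mesenchymal, endothelial and blood cells that were higher in the acinar samples. Position therefore does not measure acinar and beta identity alone. Dcn, one of these markers, was at 11.4 in acinar samples, 5.86 at day 10, 9.6 at day 30 and 11.9 at day 60. How far such markers moved the position was not tested. Induced cells lay at 0.460 ± 0.001 (SD, n = 3) at day 10, 0.528 ± 0.001 at day 30, 0.473 ± 0.049 at day 60 and 0.473 ± 0.049 at 7 months. On genes higher in beta cells the positions were 0.538, 0.631, 0.609 and 0.608, and on genes higher in acinar cells 0.386, 0.429, 0.344 and 0.346. An exact permutation F-test over the 4 times gave p = 0.181 (adjusted p = 0.326 over 18 tests of position) among 15400 assignments, whose smallest possible p is 6.5e-05. For genes higher in beta cells the exact p was 0.0306 (adjusted p = 0.200) and for genes higher in acinar cells 0.0963 (adjusted p = 0.200). Pairs of times with n = 3 each cannot give an exact two-sided permutation p under 0.1. Over all 7106 genes, and on those higher in acinar cells, day 30 reached 0.1 against day 10 and against day 60. On genes higher in beta cells, day 60 against day 30 gave a permutation p of 0.4. There day 30, day 60 and 7 months each reached 0.1 against day 10. The exact p of the F-test was 0.0130 with median scaling and 0.0010 in the matrix. These permutations treat the 12 arrays as exchangeable and ignore that same-numbered arrays of day 60 and 7 months deviate together, so that their p-values are only nominal. Over day 10, day 30 and day 60 alone, a test chosen after seeing the data, p was 0.0786 among 280 groupings.

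Many genes that separate beta from acinar cells still differed from beta cells in induced cells. Of 3766 genes higher in beta cells, 2301 (61.1%) were still below beta cells at day 10, 2226 (59.1%) at day 30, 2489 (66.1%) at day 60 and 2487 (66.0%) at 7 months. Of the same 3766 genes, 2281, 2500, 2352 and 2351 lay above acinar cells, whether or not they were still below beta cells. Of 3340 genes higher in acinar cells, 1860 (55.7%), 1712 (51.3%), 1902 (57.0%) and 1901 (56.9%) were still above beta cells. These counts take differences of any size, and the genes higher in acinar samples include markers of mesenchymal, endothelial and blood cells. Past 2-fold, 1335, 1025, 1144 and 1149 of the 3766 genes were still below beta cells. Of the 3340 genes, 1061, 846, 961 and 956 were still above them past 2-fold. Other genes went further than the target or the other way. Of the 3766 genes 851, 739, 550 and 562 lay above beta cells, and of the 3340 genes 612, 403, 392 and 401 lay above acinar cells. In a simulated group at the beta mean, tested against simulated beta arrays, 0 genes were still below and 0 still above. No gene of that group was given a difference from beta cells, so the adjusted test was bound to call almost none. The simulated noise was independent and pooled over groups, without the larger spread and the pairing of the late arrays. With other scalings the sets themselves differed, since 6258 genes were higher in beta cells and 1527 in acinar cells with median scaling, and 7044 and 926 in the matrix. At day 10, 4163 (66.5%) were then still below and 1060 (69.4%) still above beta cells with median scaling, and 4557 (64.7%) and 749 (80.9%) in the matrix.

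**Figure D2:**
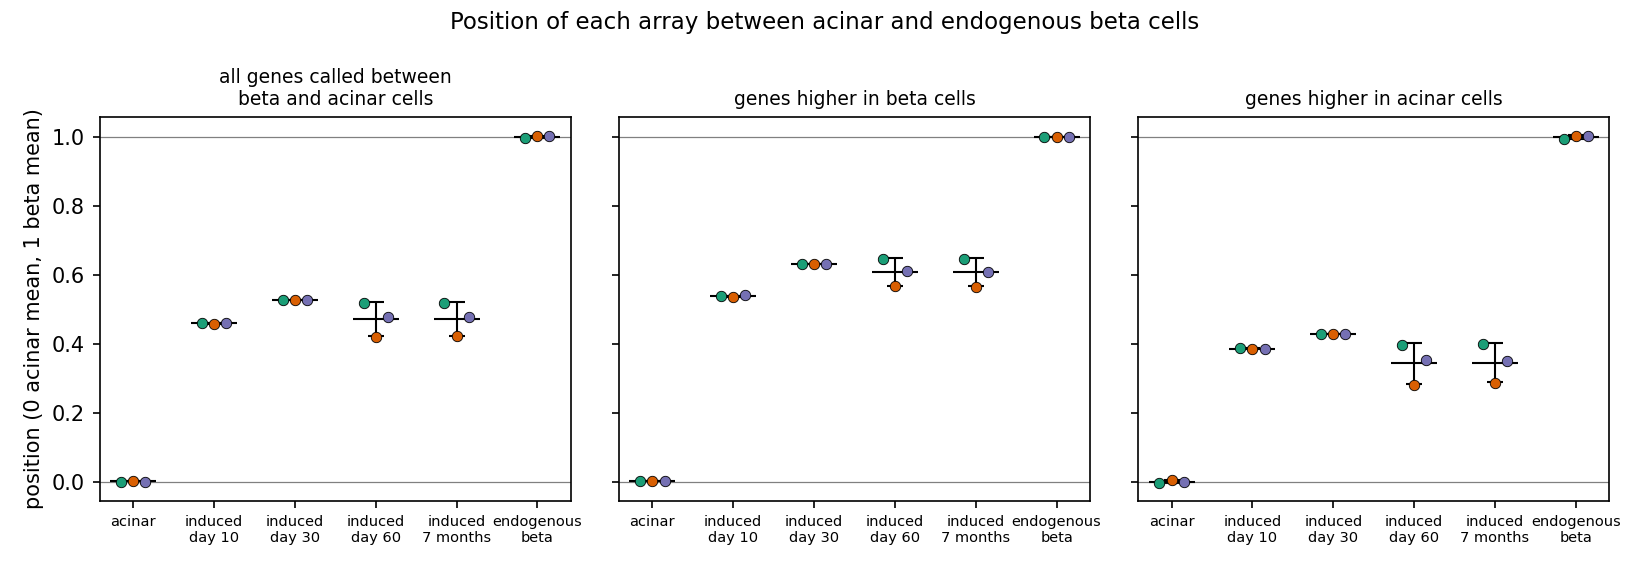
Position of each of the 18 arrays (points, coloured by replicate number) between the acinar mean at 0 and the beta mean at 1 (vertical axis, no unit), by group (horizontal axis), for all genes called between these cells and for those higher in either, where wide bars are means and whiskers are SD. Day 10 and day 30 arrays sat at 0.460 and 0.528 with little spread, and day 60 arrays ranged from 0.421 to 0.519.

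Between day 10 and day 30, genes of maturing beta cells rose. Ucn3 rose by 3.45 ± 0.14, Iapp, for the islet amyloid peptide amylin, by 2.95 ± 0.20 and Ins1 by 1.93 ± 0.092. Of 14 maturity genes 10 rose and 4 were not called (median 0.60, range 0.45 to 0.97, adjusted p = 0.00049), a list that was not called without the 27 genes with more digits (median 0.52, adjusted p = 0.154). Insulin and granule genes rose in 17 of 23 cases and fell in 1, or rose in 20 when adjusted over the list alone (median 1.11, or 0.58 at bounds, range 0.54 to 1.10, adjusted p = 1.2e-06, adjusted p = 0.0598 with an estimated correlation). Neurog3, a factor of endocrine progenitors, fell by 1.40 ± 0.38, and Gast, the gastrin gene, by 3.09 ± 0.21. Unfolded protein response genes rose in 13 of 19 cases, or rose in 14 and fell in 1 over the list alone (median 0.58, range 0.51 to 1.01, adjusted p = 0.0028, adjusted p = 0.331 with an estimated correlation). Immediate early and heat shock genes rose in 16 of 19 cases and fell in 2 (median 1.14, range 0.71 to 1.30, adjusted p = 8.3e-06, adjusted p = 0.0563 with an estimated correlation), with Hspa1a up by 2.63 ± 0.11. Dcn rose by 3.77 ± 0.27. Macrophage markers fell in 22 of 24 cases (median −1.29, or −1.26 at bounds, range −1.29 to −0.80, adjusted p = 1.5e-05, adjusted p = 0.502 with an estimated correlation). Antigen presentation genes fell in 10 of 11 cases (median −0.61, range −0.61 to −0.19, adjusted p = 0.0018, adjusted p = 0.259 with an estimated correlation). Ribosomal protein genes fell in 15 of 24 (median −0.33, range −0.49 to −0.27, adjusted p = 0.00024, adjusted p = 0.201 with an estimated correlation). The comparison called 5470 genes, 2788 higher and 2682 lower, 842 past 2-fold. The share higher was 51.0%, 68.3% with median scaling and 84.2% in the matrix, where the all-gene median lay at 0.18 and 0.26.

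Between day 30 and day 60, several islet transcription factors rose further. Rfx6 rose by 1.97 ± 0.075 and Nkx2-2, a homeodomain factor of endocrine cells, by 2.13 ± 0.11, and 8 of 13 islet transcription factors rose, 1 fell and 4 were not called (median 0.76, range −0.17 to 0.76, adjusted p = 0.0091, adjusted p = 0.198 with an estimated correlation). Without the 27 genes with more digits this list had a median of −0.17 and adjusted p = 0.647. Tdh, for the mitochondrial enzyme threonine dehydrogenase, was at least 11.5-fold lower and detected on 1 of 3 day 60 arrays, Gip fell by 2.99 ± 0.40, and Nnat, for the islet protein neuronatin, was at least 5.75-fold lower. Slpi, a secreted protease inhibitor gene, rose by 3.40 ± 0.57 and Dcn by 2.24 ± 0.27. Mesenchymal markers rose in 14 of 19 cases, or rose in 15 and fell in 1 over the list alone (median 1.59, or 1.55 at bounds, range 0.78 to 1.59, adjusted p = 0.0038, adjusted p = 0.662 with an estimated correlation). Endothelial markers rose in 10 of 14 and fell in 1 (median 0.90, or 0.84 at bounds, range 0.16 to 0.91, adjusted p = 0.0081, adjusted p = 0.440 with an estimated correlation). Macrophage markers rose in 14 of 24 cases and fell in 2, or rose in 16 over the list alone (median 1.00, or 0.87 at bounds, range 0.36 to 1.00, adjusted p = 0.0125, adjusted p = 0.716 with an estimated correlation). Interferon-stimulated genes rose in 11 of 21 cases and fell in 2 (median 0.51, or 0.48 at bounds, range 0.10 to 0.51, adjusted p = 0.0178, adjusted p = 0.482 with an estimated correlation). Without induced day 60 replicate 2 the last 2 lists were not called (median 0.56, adjusted p = 0.0858, and median 0.31, adjusted p = 0.0671), and the mesenchymal median was 1.03. The comparison called 5531 genes, 2705 higher and 2826 lower, 1178 past 2-fold. Of called genes 48.9% were higher, against 38.5% with median scaling and 31.7% in the matrix, where the all-gene median lay at −0.12 and −0.15.

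Between day 60 and 7 months no gene passed the test. Ins1 differed by 0.11 ± 0.092, Ucn3 by −0.01 ± 0.14, Mafa by 0.03 ± 0.13 and Cpa1 by 0.08 ± 0.066 (adjusted p = 1 for each). Limma called 0 of 8942 genes, with 200 at an unadjusted p under 0.05 and a largest difference of 0.77, and camera called 0 of 27 lists. Camera called 2 lists with median scaling, 3 in the matrix, 6, 7 and 2 without day 60 replicates 1, 2 and 3 in turn, and 4, 5 and 1 without the same replicates of 7 months. In simulated data for this comparison, 78.0% of genes changed 1.5-fold and 94.5% of genes changed 2-fold were called. That simulation drew independent noise with each gene's spread pooled over all groups. It held neither the larger spread nor the pairing of the late arrays, so these shares do not give the power of this comparison. Arrays of the 2 times with the same replicate number were closer to each other than arrays of the same time. The SD of their log2 differences over genes was 0.157 to 0.173, against 0.367 to 0.459 within either time. Within the triplicates of the other groups it was 0.118 to 0.239. Xist, which is expressed from the inactive X chromosome of females, had signals of 201, 66.1 and 59.8 in day 60 replicates 1, 2 and 3 and of 175, 61.6 and 61.0 in those of 7 months. Eif2s3y, a Y chromosome gene, had 72.1, 343 and 346 at day 60 and 73.1, 287 and 281 at 7 months. It had 251 to 332 in acinar cells and 979 to 995 in beta cells. At day 10 it had 168 to 181, and at day 30 it had 134 to 146. Ddx3y, also on the Y chromosome, was likewise lowest in replicate 1 of both late times. Sex was not tested as a cause of any difference. With the number as a block among the 6 late arrays, limma again called 0 genes, 555 had an unadjusted p under 0.05, and the median absolute difference was 0.05.

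**Figure D3:**
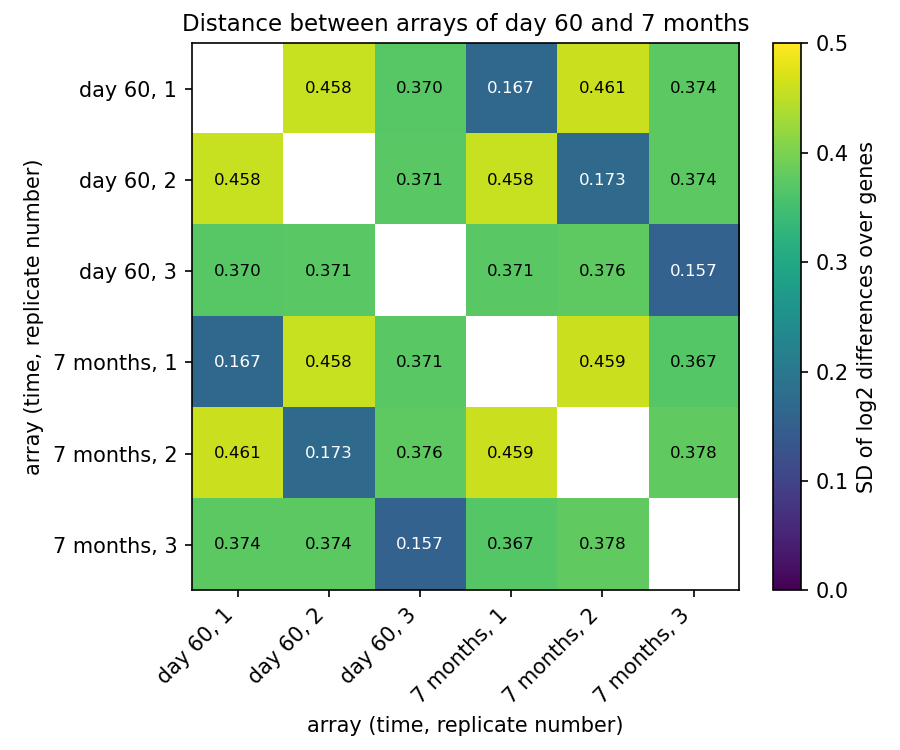
SD over genes of the log2 differences between each pair of the 6 arrays of day 60 and 7 months (both axes list arrays by time and replicate number, the colour gives the SD in log2 units). The 3 pairs with the same number had values of 0.157 to 0.173, and pairs within a time 0.367 to 0.459.

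Between day 10 and 7 months, stromal genes and some islet genes rose while mitochondrial genes fell. Dcn rose by 5.98 ± 0.27, Pdpn, for the membrane glycoprotein podoplanin, at least 31.2-fold, Hspa1a by 4.50 ± 0.11, Iapp by 4.32 ± 0.20 and Rfx6 by 4.18 ± 0.075, where the 7-month values of Iapp and Rfx6 are among those with more digits. Mesenchymal markers rose in 16 of 19 cases (median 2.57, or 2.49 at bounds, range 0.99 to 2.64, adjusted p = 0.00035, adjusted p = 0.582 with an estimated correlation). Endothelial markers rose in 11 of 14 cases (median 1.02, or 0.65 at bounds, range 0.20 to 1.02, adjusted p = 0.0081, adjusted p = 0.440 with an estimated correlation). Immediate early and heat shock genes rose in 17 of 19 cases and fell in 1 (median 1.59, adjusted p = 4.9e-06, adjusted p = 0.0513 with an estimated correlation). Islet transcription factors rose in 9 of 13 cases and fell in 2, or rose in 10 over the list alone (median 0.83, range 0.23 to 0.93, adjusted p = 0.0062, adjusted p = 0.169 with an estimated correlation). Insulin and granule genes rose in 16 of 23 and fell in 4, or 5 over the list alone (median 1.23, or 0.87 at bounds, range 0.29 to 1.23, adjusted p = 0.0037, adjusted p = 0.283 with an estimated correlation). Maturity genes rose in 9 of 14 and fell in 3, or 4 over the list alone (median 1.19, range −0.18 to 1.27, adjusted p = 0.0097, adjusted p = 0.107 with an estimated correlation). Without the 27 genes with more digits these 3 lists were not called, with medians of 0.28, 0.29 and −0.18 (adjusted p = 0.5002, 0.649 and 0.902). Oxidative phosphorylation genes fell in 21 of 29 cases and rose in 2, or fell in 22 over the list alone (median −0.59, or −0.58 at bounds, range −1.12 to −0.51, adjusted p = 0.00023, adjusted p = 0.184 with an estimated correlation). Ndufb9, a complex I subunit gene, fell by 3.19 ± 0.14. Ribosomal protein genes fell in 17 of 24 and rose in 1 (median −0.35, range −1.02 to −0.30, adjusted p = 0.0052, adjusted p = 0.335 with an estimated correlation). Antigen presentation genes fell in 10 of 11 (median −0.73, adjusted p = 0.0085, adjusted p = 0.335 with an estimated correlation). Tdh was at least 25.9-fold lower and the T cell receptor chain gene Cd3e at least 5.54-fold, detected at 7 months on 2 and 1 of 3 arrays, while the 2 lymphocyte markers were not called as a list (adjusted p = 0.176). Duct markers were not called, with 9 of 21 higher and 9 lower, or 10 higher over the list alone, and with a median of 0.79, or 0 at bounds, and a mean of 0.19 against a downward test (adjusted p = 0.908). The comparison called 6713 genes, 3171 higher, 3542 lower and 2471 past 2-fold.

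Over the 4 induced times together, an F-test called 7506 genes, 3060 with a range of at least 2-fold between group means. The widest ranges were those of Dcn at 6.01, which went from 5.86 at day 10 to 11.9 at day 60 against 11.4 in acinar cells and no detected level in beta cells, and of Iapp at 4.64, leaving aside Pdpn and Tdh, whose lowest means rest on arrays that did not all measure them. Hspa1a ranged over 4.55, from 8.57 at day 10 to 13.1 at day 60, with 8.83 in beta cells and no detected level in acinar cells.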

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

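The tests of the 3 patterns below were chosen only after the results were seen, whereas the counts over other splits of the arrays were planned.

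Gene lists were singled out where their difference from acinar or beta cells was not the same at day 10 and at 7 months, by camera's test of 7 months against day 10. Higher at 7 months were mesenchymal and stellate markers (median 2.57, adjusted p = 0.00035), immediate early and heat shock genes (1.59, adjusted p = 4.9e-06), insulin and granule genes (1.23, adjusted p = 0.0037), beta-cell maturity genes (1.19, adjusted p = 0.0097), endothelial markers (1.02, adjusted p = 0.0081), islet transcription factors (0.83, adjusted p = 0.0062) and neuronal genes shared with islets (0.83, adjusted p = 0.0097). Lower were antigen presentation genes (−0.73, adjusted p = 0.0085), oxidative phosphorylation genes (−0.59, adjusted p = 0.00023) and ribosomal protein genes (−0.35, adjusted p = 0.0052). Without the 27 genes with more digits, insulin and granule genes (0.29, adjusted p = 0.649), islet transcription factors (0.28, adjusted p = 0.5002) and maturity genes (−0.18, adjusted p = 0.902) were not called and the last turned in sign, whereas neuronal genes were called (0.77, adjusted p = 0.0197). With an estimated correlation no list was called, and the adjusted p values ran from 0.0513 for immediate early genes and 0.0711 for neuronal genes to 0.582 for mesenchymal markers. The sizes depended on the settings as well. Medians were 0.99 for mesenchymal and 0.20 for endothelial markers with limma's own inference of the negative controls, and 0.23 for islet transcription factors and 0.20 for neuronal genes with no filter on dim genes. They were −1.12 for oxidative phosphorylation and −1.02 for ribosomal protein genes with median scaling, and the neuronal median was 0.54 without 7-month replicate 3.

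For 12 of the 13 comparisons, 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, gave as many genes, with real counts of 5470 to 7151 and a highest other count of 0, and 10 splits are too few for a share under 0.05. For 7 months against day 60 the real split called 0 genes, so all 10 splits called as many, and the highest other called 1414. The splits that part all 3 same-numbered pairs, the real one among them, called 0 genes, whereas those that part 1 pair called 351 to 1414, which points to a structure among these arrays along the replicate numbers. For the F-test over the induced times, 1 of 100 regroupings, the real one with 7506 genes, gave as many, and the highest other gave 6520. This share treats the 12 arrays as exchangeable, whereas same-numbered late arrays deviate together and tight triplicates may be technical, so that chance is not excluded for this count.

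Same-numbered arrays of day 60 and 7 months lay closer to each other than arrays of the same time. A processing batch shared by all arrays of a number is argued against by the other groups, where same-numbered arrays correlated at 0.069 at most in their deviations. Expression that no longer changed between these times would not by itself make numbers match, and different-numbered arrays lay at least 2.14 times as far apart as same-numbered ones. The same RNA or tissue measured again under the later label is a candidate explanation, since the largest spread of a same-numbered pair, 0.173, lay below the 0.239 reached within the other triplicates. Not all triplicates were wider than the same-numbered pairs, at 0.157 to 0.173. Acinar arrays lay at 0.21 to 0.24 and day 10 arrays at 0.183 to 0.192, but day 30 arrays at 0.141 to 0.142 and beta arrays at 0.118 to 0.119. Tissue digested to single cells at day 60 cannot be collected again at 7 months. Whether animals of both times came from the same litters remains open and was not tested.

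In the 7-month columns the values of 27 genes carry more digits than all other values. A number format unrelated to the gene is argued against, because 20 of the 27 stand in the 4 fixed islet lists, against at most 3 in 2000 random sets. For values recalculated to a different level, the median change of these genes from day 60 to 7 months in the signals was taken. It was −0.15, just outside the −0.14 to −0.10 of random sets of like brightness. This margin is narrow. The random sets were not matched for genes that vary together, as islet genes may, so their range may be too narrow. The test therefore cannot decide on recalculated values, which remain open, and no biological explanation was tested.

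Digestive enzyme transcripts stayed near the acinar level in the induced cells. Unchanged acinar cells or their RNA at a single share were tested on 198 genes seen in the acinar samples and not in beta cells. At each time 53.5% or more of these genes lay over 2-fold from their median share. These genes were not chosen as specific to acinar cells, and the acinar samples also held markers of mesenchymal, endothelial and blood cells. The test therefore cannot decide on admixture, which remains open beside the sort for the fluorescent protein. Signals too bright to differ cannot be told apart from kept expression, because 0 of the 2 enzymes under 0.25 of the top acinar signal stayed within 2-fold. Quantile normalization also stays open, since the lowest median of the list without it was −0.94. Incomplete silencing of acinar genes, a biological explanation, may hold as well and was not tested.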

How the results depend on the processing

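Added after seeing the data were limma's own inference of the negative controls, leaving out the 27 genes with more digits or the 7-month arrays, triplicates counted as 1 sample, the block within the late arrays and day 60 in place of 7 months, and the scope of the named results was settled then too. Of 1141 values of 94 list results under alternatives other than leaving out an array, 1017 kept direction and side of the threshold, 78 were weaker, 42 stronger and 4 reversed in their median's sign. These were oxidative phosphorylation genes against acinar cells in the matrix at day 60 (0.42) and 7 months (0.28), and, without the 27 genes, islet transcription factors from day 30 to day 60 (−0.17) and maturity genes from day 10 to 7 months (−0.18). Of 7205 values of 655 gene results 7076 kept both, 44 were weaker, 55 stronger and 30 reversed. Leaving out each array, 1677 of 1692 list values and 11652 of 11724 gene values kept both and 0 reversed. The 94 were chosen after the results were seen. Over all 351 list results the median's sign turned in 27 of 3159 values and camera's direction in 9, and in 13 and 10 of 6318 values without an array, all 13 and 10 between day 60 and 7 months.

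With median scaling, signs turned for Pdx1 against acinar cells (day 10 0.076, day 30 0.17, day 60 0.89, 7 months 0.75) and between day 10 and day 30 (0.094), Gcg at day 30 against acinar cells (0.23), Ptf1a at day 10 (0.47), Ins2 at day 10 against beta cells (0.020), Ucn3 against beta cells (day 60 −0.24, 7 months −0.36) and Cpa1 from day 30 to day 60 (−0.32) and day 10 to 7 months (−0.57). In the matrix they turned for Pdx1 (0.35, 0.57, 1.11, 0.95 and 0.22 in that order), Mafa between day 10 and day 30 (0.44), Gcg at day 30 (0.70), Ppy at day 10 (0.021), Ptf1a at day 10, day 60 and 7 months (0.71, 0.43, 0.32), Ucn3 (−0.22, −0.39), Cpa1 (−0.35, −0.42), and, in beta against acinar cells, Bhlha15 (0.093), Esam (0.31) and Insig1 (0.031). The cause was not tested.

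Genes still below and above beta cells numbered 4163 and 1060 (day 10), 3602 and 1069 (day 30), 4350 and 1147 (day 60), and 4612 and 1104 (7 months) with median scaling, and 4557 and 749, 3389 and 822, 4377 and 809, and 4833 and 785 in the matrix. The exact p for position fell to 0.0130 and 0.0010, was 0.0786 without the 7-month arrays, and ranged from 0.0814 to 0.289 without each array. Mean positions with median scaling were 0.442, 0.567, 0.485 and 0.462, and in the matrix 0.499, 0.679, 0.578 and 0.536. Lists called numbered 41 with an estimated correlation, 280 by fry's direction and 307 by its mixed p. Between day 60 and 7 months 2 lists were called with median scaling, 3 in the matrix, and 0 to 7 without each array, where leaving out a late array breaks a pair. With triplicates as 1 sample, acinar, day 10, day 30 and beta cells have a lone sample each and all spread comes from the 3 arrays of 1 late time, so these counts say nothing on stability. The counts against acinar cells were 4140 (beta), 4170, 3841, 4315 and 4270, against beta cells 4164, 2788, 4090 and 4000, and 0 (day 30 against day 10), 1116 (day 60 against day 30) and 3644 (7 months against day 10). The replicate block left 0 genes called between day 60 and 7 months and ended no call, and 6 values gained one under it. Medians of the 82 called lists moved over 1.5 times in 48 with limma's own inference, 23 in the matrix, 22 with an offset of 50, 15 with no filter, 14 with median scaling, 12 with no background correction, 11 without the 27 genes, 6 with a detection p under 0.05 and 0 with the block. Day 60 in place of 7 months compares near copies with the same day 10 arrays, so its agreement says nothing on stability. The mean over probes and the slide as a block were not run. Signal over background limits dim genes, for which only bounds are given.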

Other observations

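The values below were picked after the results were seen, and no explanation of them was tested.

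Gal, the gene of the neuropeptide galanin, was higher in acinar and induced cells than in beta cells. It had a mean of 13.05 in acinar cells, 13.85 at day 10, 13.27 at day 30, 12.30 at day 60 and 12.25 at 7 months, against 5.74 in beta cells. Acta1, the skeletal muscle actin gene, had means of 4.38 in acinar cells, where it was not detected, 12.07 at day 10, 12.47 at day 30, 11.67 at day 60 and 11.65 at 7 months, against 6.89 in beta cells. In acinar cells Ins1 had deposited signals of 44.9, 43.0 and 38.5 with detection p-values of 0.0047, 0.0047 and 0.0062, below the negative controls' means of 51.0, 49.9 and 53.6, and on replicate 3 it was the lowest of 18118 symbols. Ins2 lay below that mean on replicate 3 alone, at 47.0. On the 15 other arrays 0 detected values lay below it.

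Between day 10 and 7 months the 8 markers of other islet hormone cells were not called (adjusted p = 0.980), with 2 higher, 2 lower and 4 not called, and their median of −0.03 and mean of 0.16 differed in sign. Gcg rose by 3.14 ± 0.38 while Rbp4, for the retinol carrier, fell by 2.54 ± 0.18. The 13 cholesterol synthesis genes were not called either (adjusted p = 0.875), with 5 higher, 6 lower and 2 not called, and a median of 0.01 against a mean of −0.08. In endogenous beta cells Mafa was at 5.28 ± 0.054 (SD, n = 3), near the floor for bounds of 5.07 to 5.43 on these arrays. This was at least 8.45-fold below the induced cells at day 10, where the arrays do not separate a viral copy from the cell's own. A value near the floor does not show that beta cells lack Mafa.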
